A study of Drosophila melanogaster with 14 samples.

How the data were processed

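The 14 arrays carried RNA of whole Drosophila heads or of anti-FLAG immunoprecipitates. Per the labels' protocols, about 100 frozen heads per whole-head sample were extracted with Trizol and a spin column, and array targets were prepared from total RNA by the manufacturer's routine. For the immunoprecipitates about 200 heads were fixed in 1% formaldehyde for 30 min and sonicated, RNA bound to FLAG-tagged poly(A)-binding protein was recovered on beads, and the crosslink was reversed by heat. Groups and replicate numbers of head samples came from the labels. The label text of the immunoprecipitates used here ends before any sample number, so those replicates were numbered in accession order, which pairs nothing.

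The deposited value table holds 1 intensity per probe set and array on a linear scale, with 14010 probe sets, values from 0 to 31791 and 4 exact zeros. The probe set algorithm, its version and the scaling target are not given in the sources used here. Medians of the deposited intensity columns ran from 180.1 to 201.8. Trimmed means (2% off each end) ran from 310.2 to 373.4, more than the 5% set beforehand as the tolerance, so each array was scaled to the mean of these. The 44 control probe sets served only as quality measures. Of the other 13966, 12442 had 1 gene, 327 several and 1197 none in the platform's gene table. Those without a gene are unnamed here, not without a gene, and none was named from a probe set with several. Among the 12442, 12393 matched by gene identifier the RefSeq gene table for assembly Release 6, no symbol changed, and they stand for 10843 genes. No coordinates are given, because no build is named for the arrays. By this table ninaE, norpA, ninaC, Rh3, Rh4, Rh5, Rh6 and w were not paired with a probe set and were not analysed here.

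Values were log2(signal + 32), so fold changes are on that scale and understate the change of low signals. Probe sets whose mean log2 value over all arrays reached the 30th percentile were tested, 9776 in all. Each comparison used only its own arrays in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over the probe sets tested. A gene is represented by its brightest probe set over all arrays, and probe sets that can share sequence with other genes make rut, Tret1-1 and Hsc70-3 uncertain, so they are not named as examples. Of the genes with several probe sets, 63 were called in both directions in IP versus Rh1 heads and 84 in Rh1 heads versus CS heads. The 21 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 3 tested genes, with an estimated correlation and fry as alternatives. Counts of list members are of genes past the filter. The planned phototransduction member Rtp did not match the symbol rtp by its spelling, so the list's counts and medians are without it and a list with it is an alternative chosen after its values were seen. The list of mitochondrial genome transcripts had 0 members measured. That of other rhodopsins had 1, which fell below the filter. The histone list had only His2Av, a variant histone (log2 fold 0.68 in IP versus Rh1 heads and 0.28 in Rh1 heads versus CS heads).

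The groups, tests, filter, gene lists, rule for named genes and most alternatives were fixed before the data were examined. That rule took the 10 largest rises and 8 largest falls in each comparison among genes past the threshold without overlap between arrays, the 2 members of each list with the largest absolute fold, and trp, trpl, Arr1, Arr2, inaD, Hdc, pAbp and repo along with the unpaired genes above. Other list members named as examples (Galphaq, Gbeta76C, TpnC73F, Mf, Mlc1, bmm, chp, eya, gl, onecut, Gli, nrv2, st, rdhB, Pdh, t, CarT, Pph13, RpS28a, GstD1 and Pxn, each where the rule did not give it) were chosen after their values were seen. Alternatives were other pseudocounts, filters and scalings (quantile, median, cyclic loess), a fit of all arrays, eBayes without trend, array weights, leaving out arrays, CS heads as reference for IP, a replicate block, the mean of all probe sets of a gene, and the set tests named above.

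The fit was tested on simulated data for 9776 probe sets with 200 changed genes in each of 10 draws. With each group's own spread, 84.6% of 2-fold and 52.1% of 1.5-fold changes were recovered for IP versus Rh1 heads, and 13.5% of calls were false. For Rh1 heads versus CS heads 99.1% and 96.6% were recovered and 9.6% of calls were false. With the same spread in both groups the share of false calls was 6.3% in each, already above the 5% aimed at, and unequal spread raised it further. These shares hold for 200 changes among 9776 probe sets. They need not hold for the real comparisons, where many more probe sets were called. No pair of replicates shared more than 1 identical value, so none was counted as a repeat deposit. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.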

Results

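RNA from Drosophila melanogaster heads was measured on 14 single-colour Affymetrix arrays, which fell into 3 groups by their labels. The first group held 6 arrays of whole heads of Canton-S, a wild-type strain (CS heads). The second held 4 arrays of whole heads of flies in which the Rh1-GAL4 driver, active in the outer photoreceptors R1-R6, was combined with a FLAG-tagged poly(A)-binding protein transgene (Rh1 heads). The third held 4 arrays of RNA recovered with anti-FLAG beads from formaldehyde-fixed heads of such flies, which the labels name photoreceptor cells R1-R6 (IP). Poly(A)-binding protein coats the tails of messenger RNA, so that tagging it in 1 cell type is a way to pull down that cell type's transcripts. The labels gave the transgene both as the fly and as the human form, and this was not settled here. Nothing in the labels said whether replicates came from separate cohorts of flies, so the p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

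The head arrays resembled each other closely, with correlations across probe sets of 0.980 to 0.994 among CS heads and 0.985 to 0.994 among Rh1 heads. The IP arrays correlated at 0.847 to 0.976 with each other, and their median SD on the log2 scale was 0.222, against 0.098 in Rh1 heads and 0.096 in CS heads. Control probe sets at the 5′ and 3′ ends of long-known housekeeping transcripts showed a loss of 5′ signal in IP. The 5′ over 3′ ratio for eIF-4a, a translation factor, was 0.645 ± 0.0305 (SD, n = 4) in Rh1 heads and 0.518 ± 0.0554 (SD, n = 6) in CS heads. In IP it was 0.531, 0.0284, 0.209 and 0.0432 for replicates 1, 2, 3 and 4.

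**Figure D1:**
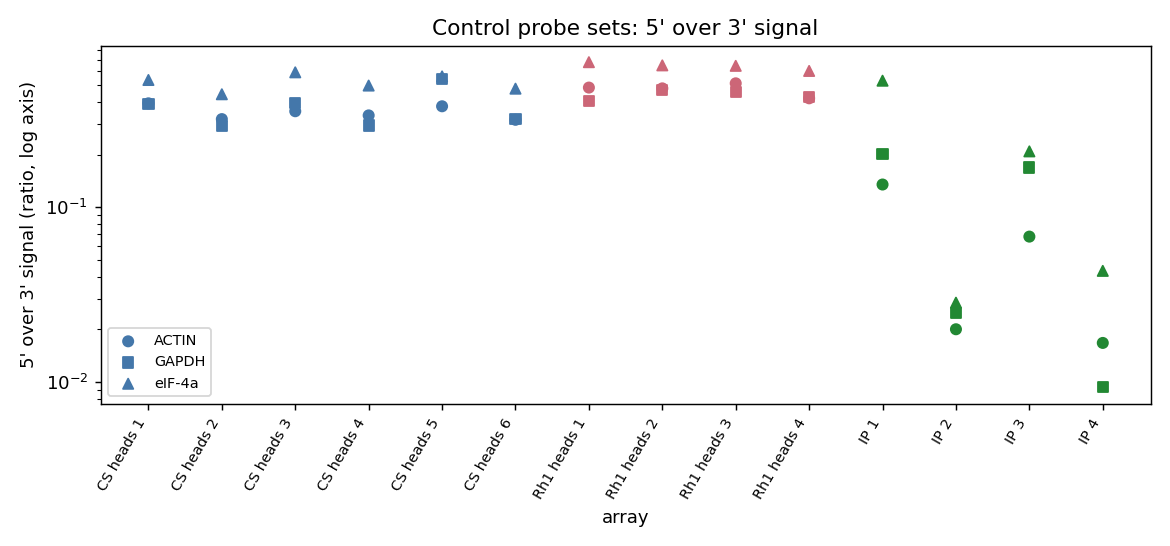
Ratio of 5′ to 3′ signal (log axis) of the actin, GAPDH and eIF-4a control probe sets on each array, with blue for CS heads, red for Rh1 heads and green for IP. For eIF-4a the head arrays lay between 0.444 and 0.678, and IP replicates 2 and 4 were at 0.0284 and 0.0432.

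The comparison of IP with Rh1 heads asked which transcripts were enriched or depleted in the RNA bound to tagged protein, against whole heads of the same genotype. The heads for IP were fixed and sonicated, and the whole heads were extracted with Trizol without any fixation given. Differences made by these steps cannot be told apart from binding to the tagged protein. Of 10 tested genes of photoreceptor fate and the rhabdomere, the light-sensing membrane stack, 7 were higher in IP (camera adjusted p = 0.00137). Of the tested genes, 13 of 14 of muscle (8.53e-07), 11 of 13 of fat body (2.91e-05) and 13 of 13 of transmitter systems of other neurons (1.06e-05) were lower, with camera adjusted p-values in parentheses. Each of these 4 lists had adjusted p = 0.0838 with an estimated correlation. Pph13, a homeodomain regulator of photoreceptor genes, had a signal of 1058 ± 64.6 (SD, n = 4) in IP and 101 ± 5.67 (SD, n = 4) in Rh1 heads, a log2 fold of 3.03 (SE 0.08). Prm, which encodes paramyosin of muscle thick filaments, had 365.8 ± 33.6 (SD, n = 4) against 3536 ± 140 (SD, n = 4), a log2 fold of -3.17 (SE 0.10). In both cases every IP array lay on 1 side of every Rh1 head array.

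In the list of photoreceptor fate and the rhabdomere 7 of 10 tested genes rose, 1 fell and 2 did not pass, with a median log2 fold of 1.62. Besides Pph13, the rises included prom (2.47) and chp (1.84), which encode membrane proteins of the rhabdomere, and the eye regulators eya (2.26) and gl (2.25), while onecut fell by 1.08. The camera test gave this list an adjusted p of 0.00137, and adjusted p = 0.0838 with an estimated correlation. Adjusted over the list alone, the counts were also 7 and 1. Of the 3 genes for histamine, the photoreceptor transmitter, 2 rose: Hdc, the synthesizing enzyme (2.84, SE 0.15), and CarT, a carrier for its recycling product (2.55, SE 0.23). The third, t, had a log2 fold of 0.72 (SE 0.77). The camera adjusted p was 0.0298, with adjusted p = 0.113 with an estimated correlation, and 2 members passed when adjusted over the list alone. Without IP replicate 1 it was 0.0555, within a range of 2.83e-06 to 0.113 over all alternatives.

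Phototransduction genes went both ways, with 7 of 17 higher, 4 lower and 6 not passing, and a median log2 fold of 0.43. The counts adjusted over the list alone were 7 higher and 5 lower. The rises included stops (3.12, SE 0.11), needed for phospholipase C stability, the light-activated channels trpl (2.74, SE 0.14) and trp (2.39, SE 0.33), and the scaffold gene inaD (2.41, SE 0.21). Galphaq fell by 1.33, at low mean signals of 266 in Rh1 heads and 91.08 in IP. Arr1, an arrestin, had 0.48 (SE 0.21, limma adjusted p = 0.0860). Other probe sets of stops gave 1.00 and 0.30. The list did not pass the camera test (adjusted p = 0.106; adjusted p = 0.609 with an estimated correlation). With rtp, a planned member left out of these counts by its spelling, it passed with a median of 0.45 (adjusted p = 0.0415), and without IP replicate 4 it passed with a median of 0.67 (adjusted p = 0.00895; range over all alternatives 0.000867 to 0.609). Without that array Arr1 passed as well, at 0.67 (limma adjusted p = 0.00014; range over all alternatives 2.41e-06 to 0.267).

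The same transcripts were low in Rh1 heads. Against CS heads as reference, the IP log2 folds were -0.51 for trpl (limma adjusted p = 0.00441), -0.11 for trp (limma adjusted p = 0.749) and -0.19 for inaD (limma adjusted p = 0.400). Over all alternatives the adjusted p ran from 1.47e-11 to 0.00441 for trpl, from 2.66e-10 to 0.749 for trp and from 5.21e-11 to 0.400 for inaD. Those of Pph13 (2.53), prom (3.07), Hdc (1.58) and stops (2.24) stayed positive.

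**Figure D2:**
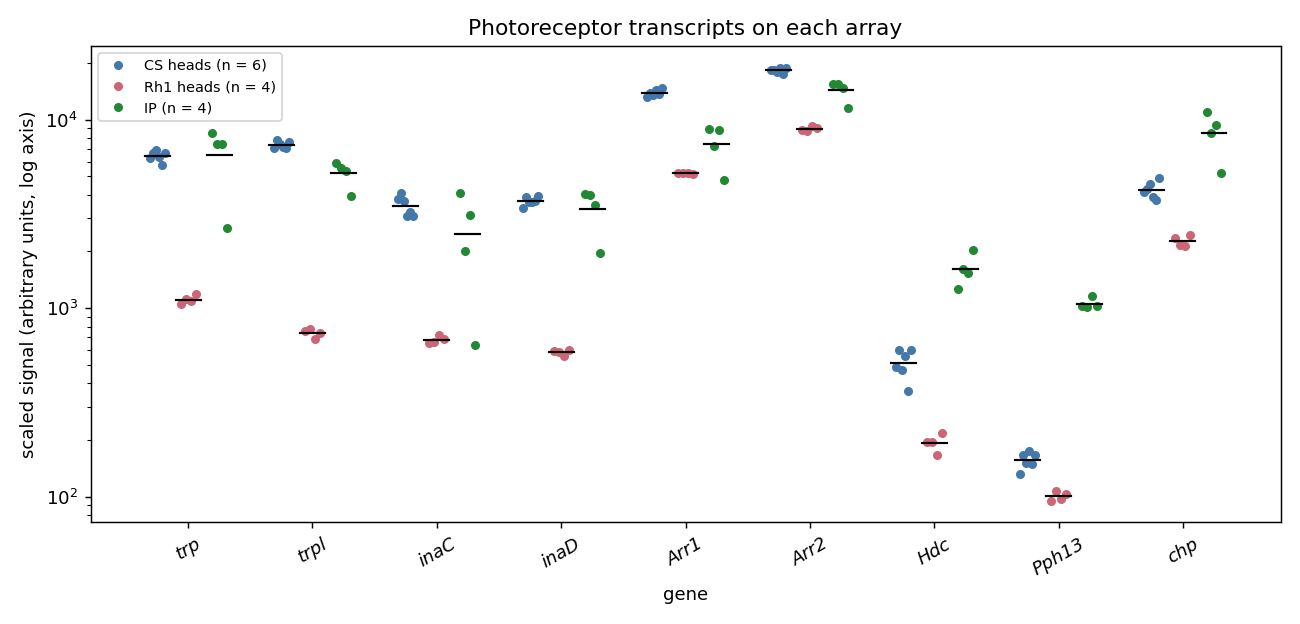
Scaled signal (arbitrary units, log axis) of 9 photoreceptor genes on each array; points are arrays and bars are group means. For trpl the mean was 7342 in CS heads, 739.8 in Rh1 heads and 5187 in IP.

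Muscle genes were lower in IP as a group, with 13 of 14 tested members lower and a median log2 fold of -2.17. The troponin gene up fell by 3.62 (SE 0.17), Mf fell by 2.75 and the myosin light chain gene Mlc1 fell by 2.56, while TpnC73F had -0.04. A second probe set of up gave -0.34. Of 13 fat body genes 11 fell, 1 rose and 1 did not pass, with a median of -2.23. The lipid carrier gene apolpp fell by 3.66 (SE 0.19), fit fell by 3.21 (SE 0.26) and the yolk protein gene Yp1 fell by 2.23 (SE 0.31), whereas the lipase gene bmm rose (0.68). Camera adjusted p-values were 8.53e-07 for muscle and 2.91e-05 for fat body, and for both adjusted p = 0.0838 with an estimated correlation. The list of sex-biased head transcripts, all of whose tested members are also in the fat body list, had 5 of 6 members lower (median -2.06, camera adjusted p = 0.00256; adjusted p = 0.0838 with an estimated correlation). Counts adjusted over the list alone were the same for these 3 lists.

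All 13 tested genes of transmitter systems of other neurons fell, out of 17 on the array, with a median log2 fold of -0.66. Gad1, the GABA-synthesizing enzyme, fell by 3.24 (SE 0.08), from 1282 ± 60.2 (SD, n = 4) in Rh1 heads to 106.7 ± 1.93 (SD, n = 4). Of 17 neuropeptide genes 12 fell, among them Ms (-2.65) and Dh31 (-2.31), and 5 did not pass. Of 7 pan-neuronal synapse genes 5 fell, among them Syn (-2.83) and unc-104 (-2.21), and 2 did not pass. Camera adjusted p-values were 1.06e-05, 5.59e-05 and 0.00250 for the lists in this order, and adjusted p = 0.0838, 0.113 and 0.0838 with an estimated correlation. Counts adjusted over the list alone were 13, 12 and 5 lower.

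Glial genes were lower in 9 of 14 cases, higher in 2 and not passing in 3, with a median of -0.57. Gat, a GABA transporter of glia, fell by 3.30 (SE 0.10), while Gli (1.17) and nrv2 (1.18) rose and repo, a glial regulator, had 0.06 (SE 0.19, limma adjusted p = 0.805). The camera adjusted p was 0.0185, with adjusted p = 0.0838 with an estimated correlation, and the counts adjusted over the list alone were 3 higher and 9 lower. The glial call was also lost with the filter at the 50th percentile (camera adjusted p = 0.0508) and with array weights (0.0654). CS heads as reference (0.106) and lists without probe sets shared between genes (0.0504) lost it too, within a range over all alternatives of 7.07e-07 to 0.106. Of 7 antennal genes 5 fell, including the odorant-binding protein genes Obp56d (-2.94) and Obp99a (-2.59), with a camera adjusted p of 0.00915 and adjusted p = 0.262 with an estimated correlation. The count adjusted over the list alone was also 5. Of 9 genes in the list of pigment and cone cells 4 rose and 5 did not pass, with a median of 0.25. Whether the members of that list are confined to these cells was not checked here. The rises were bw (2.23, SE 0.09) and st (0.75), transporters of eye pigment precursors, santa-maria (1.12, SE 0.13), a scavenger receptor of carotenoid uptake, and rdhB (0.98). Pdh, an abundant retinal dehydrogenase transcript, had -0.20 (SE 0.18), and a second probe set of bw gave -0.26. The camera adjusted p was 0.0186, with adjusted p = 0.127 with an estimated correlation, and 4 rose when adjusted over the list alone.

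Heat shock and stress genes were higher in 4 of 9 cases, with Hsp26 at 2.83 (SE 0.14) and Hsp27 at 1.85 (SE 0.14), lower in 3, and had a camera adjusted p of 0.272. Of 8 clock genes 3 rose, including tim (1.5, SE 0.16; a second probe set gave -0.53), and 3 fell, including Pdp1 (-1.22), with a camera adjusted p of 0.968. Hemocyte genes fell in 4 of 6 cases, including the collagen genes Col4a1 (-2.30) and vkg (-1.66), and 1 rose by at least 2-fold. Their camera adjusted p was 0.0808 (0.0441 without IP replicate 4, range over all alternatives 0.000313 to 0.449). Immune genes fell in 5 of 9 cases, Drs at -1.41, and rose in 2, CecB at 1.27 (camera adjusted p = 0.317). Of 33 cytosolic ribosomal protein genes 6 rose, including RpL7-like (1.40) and RpS28a (0.93), and 1 fell (camera adjusted p = 0.147; 0.00264 without IP replicate 4; range over all alternatives 0.00181 to 0.627). Of 58 nuclear genes of oxidative phosphorylation 20 fell, including Cyt-c1 (-2.33) and ATPsynO (-1.69), and 4 rose (median -0.39, camera adjusted p = 0.0315; adjusted p = 0.609 with an estimated correlation). Without Rh1 head replicate 2 the last list had 0.0876, within a range over all alternatives of 0.000239 to 0.609. Adjusted over the list alone, the counts higher and lower were 5 and 3 for heat shock, 3 and 3 for clock, 1 and 4 for hemocyte, 3 and 5 for immune, 5 and 0 for ribosomal protein and 4 and 19 for oxidative phosphorylation genes.

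Outside the lists, the steepest rises were those of ZnT35C, a zinc transporter gene (3.58, SE 0.11), CG15369 (3.31, SE 0.23), Atx-1 (3.12, SE 0.68) and SmydA-8 (3.06, SE 0.12), followed by Rbp9, a neuronal RNA-binding protein gene (2.96, SE 0.14). The steepest falls were those of CG5172 (-4.34, SE 0.11), Cyt-b5-r (-3.90, SE 0.16), CG8329 (-3.77, SE 0.20) and CG2269 (-3.66, SE 0.24). Against CS heads as reference their IP log2 folds were -1.55, -3.94, -2.80 and -2.99 in this order. The fly gene for poly(A)-binding protein, pAbp, had 0.28 (SE 0.19, limma adjusted p = 0.249), and 1.12 on its other probe set. It passed with quantile scaling (0.61, limma adjusted p = 0.0198), array weights (0.29, 0.0133) and CS heads as reference (0.51, 0.0132). Without IP replicates 2 and 4 it passed as well (0.46, limma adjusted p = 0.00341; range over all alternatives 0.00341 to 0.460). Whether the pAbp probe sets also read the transgene is not known here.

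Over all 9776 probe sets tested with limma, 4630 passed at an adjusted p under 0.05, with 2131 higher and 2499 lower in IP. Of these, 684 were higher and 880 lower by at least 2-fold. The arrays of the groups did not overlap for 46.6% of probe sets, where chance gives 2.86%. In simulated data with each group's own spread, 13.5% of calls were false, but only 200 of 9776 probe sets were changed there. That share need not hold where 4630 pass. With array weights the count was 6969. Without IP replicates 2 and 4, left out after their 5′ loss had been seen, it was 5470. The excess of lower calls depended on the scaling, as 53% of calls were higher with median scaling against 46% here.

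**Figure D3:**
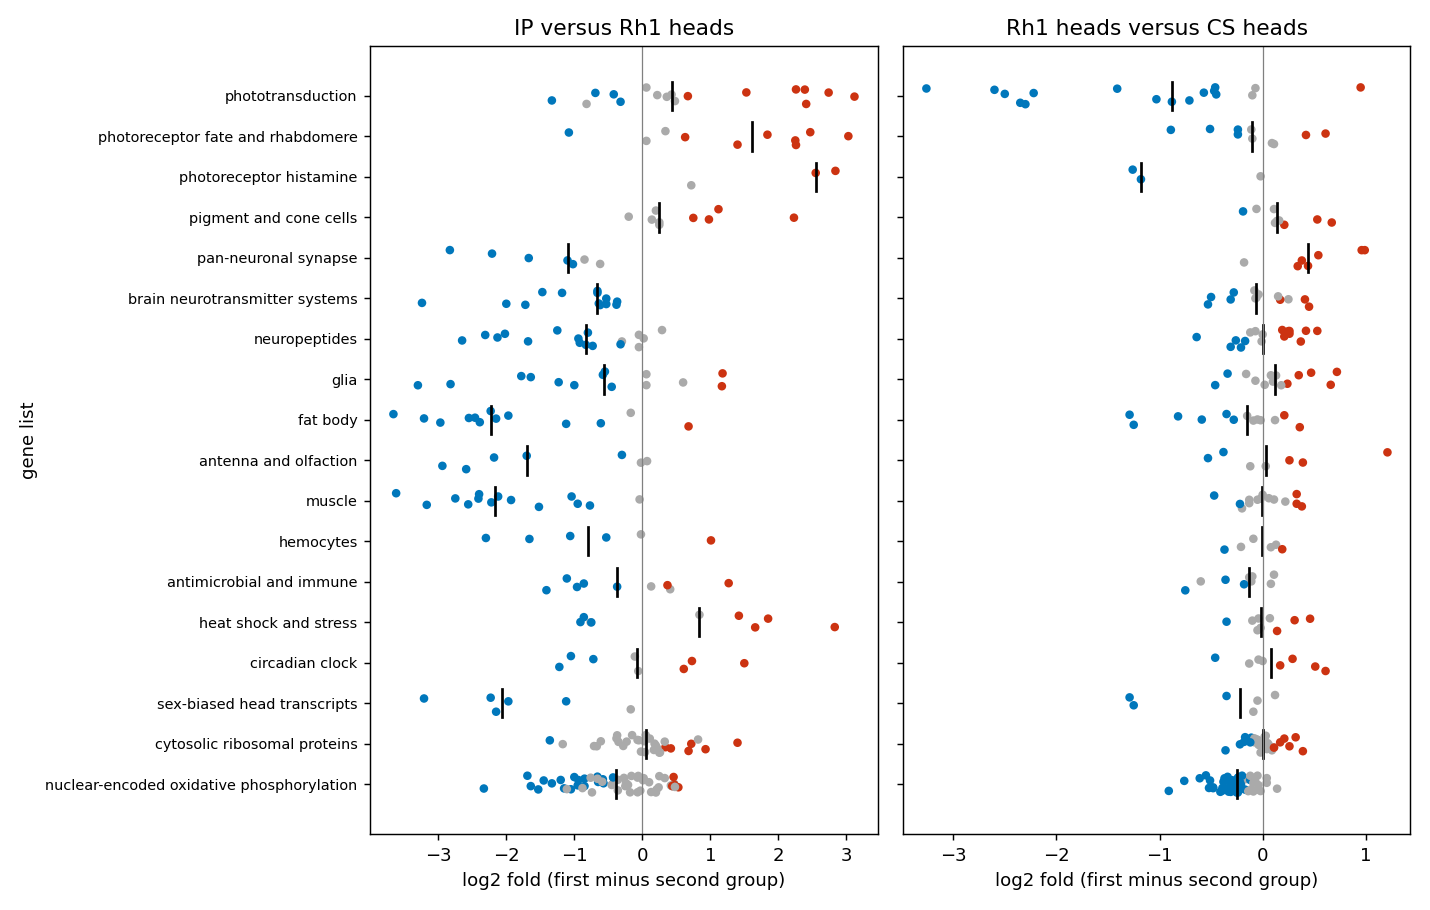
Log2 fold of each tested member of the gene lists with 3 or more tested genes, for IP minus Rh1 heads (left) and Rh1 heads minus CS heads (right); red and blue mark members that passed as higher or lower, grey those that did not, and black bars the list medians. The phototransduction median was 0.43 on the left and -0.88 on the right, and the muscle median was -2.17 on the left and -0.01 on the right.

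The comparison of Rh1 heads with CS heads showed how heads carrying the driver and the tagged protein differed from wild-type heads. Transcripts of the light response were lower in Rh1 heads. The channel genes trpl and trp fell by 3.26 (SE 0.06) and fell by 2.50 (SE 0.06) on the log2 scale. The signal of trpl was 739.8 ± 35.2 (SD, n = 4) in Rh1 heads and 7342 ± 312 (SD, n = 6) in CS heads, and that of trp 1112 ± 61.2 (SD, n = 4) and 6431 ± 394 (SD, n = 6). The limma adjusted p was 3.71e-14 for trpl and 1.31e-12 for trp, and for both every Rh1 head array lay below every CS head array.

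Of 17 phototransduction genes 14 fell, 1 rose and 2 did not pass, with a median log2 fold of -0.88, and the counts were the same adjusted over the list alone. Further falls were those of inaD (-2.60), the G protein subunit genes Ggamma30A (-2.35) and Gbeta76C (-2.22), the protein kinase C gene inaC (-2.30) and the arrestin genes Arr1 (-1.41) and Arr2 (-1.03). Galphaq rose (0.95). The camera adjusted p was 9.13e-10, and this was the list of this comparison that passed in both ways, with adjusted p = 0.00828 with an estimated correlation. Of the histamine genes, Hdc fell by 1.26 (SE 0.12) and t fell by 1.18 (SE 0.08), while CarT had -0.02. The mean signals of CarT were low, at 63.64 in CS heads and 60.13 in Rh1 heads, where a fall could hardly be seen. That list had a camera adjusted p of 0.118, which was 0.0445 without CS head replicate 5 (range over all alternatives 0.000374 to 0.460), and 2 fell when adjusted over the list alone.

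Genes of photoreceptor fate and the rhabdomere were lower in 4 of 10 cases, including chp (-0.89, SE 0.08) and Pph13 (-0.51), and higher in 2, including prom (0.61, SE 0.05), with a median of -0.10 and a camera adjusted p of 0.810. The counts adjusted over the list alone were 4 and 2. In the list of pigment and cone cells 3 of 9 genes rose, including ninaB (0.67) and bw (0.53), and 1 fell (camera adjusted p = 0.133). The counts were the same adjusted over the list alone. Pan-neuronal synapse genes were higher, with 6 of 7 rising and a median of 0.44, including unc-13 (0.99, SE 0.13) and Syn (0.96, SE 0.12). The camera adjusted p of that list was 0.0162, with adjusted p = 0.434 with an estimated correlation, and 6 rose when adjusted over the list alone. Nuclear genes of oxidative phosphorylation were lower in 41 of 58 cases and higher in 0, with a median of -0.25, and included ND-PDSW (-0.91) and COX7A (-0.76). Their camera adjusted p was 1.68e-06, with adjusted p = 0.467 with an estimated correlation, and 42 fell when adjusted over the list alone.

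Among fat body genes 6 of 13 fell and 2 rose, and fit (-1.29, SE 0.15) and Obp99b (-1.25, SE 0.17) moved furthest (camera adjusted p = 0.191). These 2 genes also moved furthest in the list of sex-biased transcripts, where 3 of 6 fell (camera adjusted p = 0.160). In the antennal list 3 rose, including Obp99a (1.21, SE 0.15), and 2 fell, including Obp28a (-0.53) (camera adjusted p = 0.820). Of 14 glial genes 5 rose, including Nrx-IV (0.72) and Gli (0.66), and 2 fell (camera adjusted p = 0.191). Of 17 neuropeptide genes 8 rose, including AstC (0.53), and 5 fell, including Crz (-0.64) (camera adjusted p = 0.676). Of 13 brain transmitter genes 3 rose and 4 fell, the latter including the GABA receptor gene Rdl (-0.53) and the dopamine transporter gene DAT (-0.50) (camera adjusted p = 0.810). Muscle genes rose in 3 of 14 cases, including sls (0.38), and fell in 2, including Mlp84B (-0.47) (camera adjusted p = 0.810). Of 6 hemocyte genes Pxn rose (0.19) and PPO2 fell (-0.37, with 1.05 on its other probe set) (camera adjusted p = 0.995). Ribosomal protein genes rose in 6 of 33 cases, including RpS12 (0.39), and fell in 6, including RpL37-2 (-0.36) (camera adjusted p = 0.810). Clock genes rose in 4 of 8 cases, including tim (0.61) and vri (0.51), and fell in 1 (camera adjusted p = 0.375). In the list of heat shock and stress genes 3 of 9 rose, including the stress gene GstD1 (0.31), and l(2)efl fell (-0.35) (camera adjusted p = 0.640). Immune genes fell in 3 of 9 cases, including PGRP-SB1 (-0.75), and rose in 0 (camera adjusted p = 0.307). For neuropeptide, muscle, heat shock and ribosomal protein genes the medians were 0.00, -0.01, -0.02 and 0.00, while the means were 0.04, 0.02, 0.04 and 0.01 and the test's direction was up. Adjusted over the list alone, muscle had 2 and 1, hemocyte 0 and 1, ribosomal protein 5 and 6, and immune genes 0 and 2 higher and lower, and the counts of the others in this paragraph did not change.

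Outside the lists, the steepest rises in Rh1 heads were those of Ugt35B1, a glucuronosyltransferase gene (3.67, SE 0.09), Sclp (3.24, SE 0.11), CG17298 (2.80, SE 0.13), CG5172 (2.79, SE 0.16), Arc1, an activity-regulated gene (2.65, SE 0.08), and the cuticle protein gene Cpr62Bc (2.21, SE 0.13). Besides the light-response genes, CG16926 (-2.61, SE 0.08), CG30054 (-2.47, SE 0.09) and Cpr72Ec (-2.26, SE 0.19) fell most. The gene pAbp had 0.23 (SE 0.08, limma adjusted p = 0.0265) and 0.76 on its other probe set. Its call was lost without Rh1 head replicate 1 (adjusted p = 0.0954) or replicate 4 (adjusted p = 0.0920), within a range over all alternatives of 0.00423 to 0.228.

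With limma, 5293 of 9776 probe sets passed, with 2386 higher and 2907 lower in Rh1 heads, but only 70 higher and 68 lower by at least 2-fold. The arrays did not overlap for 38.8% of probe sets, where chance gives 0.95%. The array titles of the head groups carry different prefixes that follow the genotype, so a batch, if the prefixes mark one, and the genotype cannot be told apart. Control probe sets that do not depend on the flies' genes also separated the head groups: BioB was at 335 to 393 in Rh1 heads and 617 to 1760 in CS heads, and CreX at 10800 to 13700 and 18100 to 24300. The actin 5′ over 3′ ratio was 0.421 to 0.513 in Rh1 heads and 0.317 to 0.394 in CS heads. With cyclic loess scaling 54% of calls were higher, against 45.1% here. In a fit of all 14 arrays, where the wider IP spread enters, 3013 passed.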

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

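The tests of scaling, equal photoreceptor loss and array run in Rh1 heads, and of 5′ loss in IP, were chosen after the results they bear on had been seen, and the spread required of both IP tests and of the test of equal loss was set after their values were seen. An array is listed where its gap to the nearest of its group is wide for the group's range; 20 of 270 groups of values met this, or 7.4%, where chance gives about 1 in 20.

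The fall of phototransduction transcripts in Rh1 heads is the first pattern weighed. The choice among the scalings run is argued against as its source. The list median closest to 0 under quantile, median or cyclic loess scaling was -0.87, against -0.88 in the main one. A shift shared by most transcripts would be hidden by each of these scalings. A smaller share of photoreceptor RNA with an equal fall for all its transcripts is not decided. The log2 folds of 7 photoreceptor genes ran from -3.26 to -0.89 with an SD of 0.71, far above their median SE of 0.06. This SD was under 3 times the SD of 0.28 between probe sets of the same gene, a bound set after the values were seen. The SD of 0.28 came from all 699 genes with several probe sets, whatever their change. It does not show how unequally probe sets read a large fall, so this bound cannot decide the question. The spread also rested largely on chp (-0.89), as the others of the 7 lay between -3.26 and -2.22. Genes of photoreceptor fate and the rhabdomere did not fall alike, with 4 of 10 lower, 2 higher and a median of -0.10. Genes also used by other cells could fall less, which was not tested. An array run following the title prefixes cannot be told apart from genotype, as 0 genotypes had arrays of both prefixes, and the hybridization controls BioB and CreX were lower on every Rh1 head array than on every CS head array. An effect of the driver, the tagged protein or the strain background stays open and untested.

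The second pattern is the lower level of muscle, fat body and brain transmitter transcripts in IP. The choice among the scalings run is argued against as its source. The median over the 40 members was -1.55 under the scaling closest to 0 (cyclic loess) and -1.82 in the main one. The first was 85.1% of the second, with a bootstrap SD of 8.7 percentage points over genes, not arrays. Each scaling brings the arrays to a common level, so a shift shared by most transcripts in IP would not be seen. Loss of 5′ sequence stays open as a part of the lower level. Without IP replicates 2 and 4 the median was -1.44, 79.2% of the main one with an SD of 11.5 points, and the arrays kept also had low actin ratios of 0.135 and 0.0679. Capture of RNA from R1-R6 cells, which the labels name, also remains possible and was not tested against a mock precipitate here. Fixation and the other steps of RNA preparation differ between the groups and cannot be told apart from capture.

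The real split of the arrays called more probe sets than any other split that was run. Chance is not excluded by this. Every other split puts arrays of both groups on at least 1 side, which widens the spread there and lowers the calls. In IP versus Rh1 heads, 1 of 35 splits of the 8 arrays, the real one, called 4630 and the highest other called 0. In Rh1 heads versus CS heads, 1 of 100 splits called 5293 and the highest other called 0. For the numbers of gene lists that camera called, the splits cannot tell chance apart either, as some of them keep part of the group difference. As many as the real 12 were called in 3 of 35 splits (highest other 12), and as many as the real 3 in 54 of 100 splits (highest other 7). A count of lists therefore has no backing from the splits and carries little weight by itself.

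CS head replicate 5 stood apart in the hybridization controls BioB (1760, others 617 to 900) and CreX (24300, others 18100 to 20200), and in the signals of CG17298 (432.8), CG3857 (339.5) and PPO2 (540.9). Rh1 head replicate 2 stood apart in the list medians of glia (0.18), antenna (-0.09) and oxidative phosphorylation (-0.13) relative to CS heads, and in the signals of CG17298 (3921), Drs (1217), sls (459.7) and Ugt35B1 (2606). Rh1 head replicate 3 did so for bw (638.1). IP replicate 4 had the lowest medians of ribosomal protein genes (-0.44, others 0.17 to 0.28) and sex-biased transcripts (-2.58) relative to Rh1 heads. IP replicate 2 had an immune median of -0.08, IP replicate 1 signals of 295.7 for Pdp1 and 5333 for rut (a probe set that can share sequence with other genes), and IP replicate 3 signals of 149.6 for CG7781 and 1155 for Pph13.

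The 3′ control probe set for actin, which no comparison used, had a mean signal of 5270 in IP, above the 427.2 to 1622 of the head arrays. In Rh1 heads it was 1520 ± 139 (SD, n = 4) and in CS heads 474 ± 42.4 (SD, n = 6).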

How the results depend on the processing

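Leaving out both IP arrays with little 5′ control signal, the phototransduction list with rtp, and lists without probe sets shared between genes, were chosen after seeing the data. Most named genes were picked by their large folds in these same data, so their steadiness says little about the other calls. Named genes mostly held: 48 of 56 in IP versus Rh1 heads and 48 of 55 in Rh1 heads versus CS heads kept direction and side of the threshold under all alternatives run. Of 18 lists each, 0 and 4 did. The share of higher calls turned with scaling: from 46% to 50.7% (quantile) and 53% (median) in IP versus Rh1 heads, and from 45.1% to 54% (cyclic loess) in Rh1 heads versus CS heads. The count of 4630 for IP versus Rh1 heads ran from 3784 to 5372 with 1 array left out, was 6969 with array weights, and 5470 without IP replicates 2 and 4. That of 5293 for Rh1 heads versus CS heads ran from 4602 to 5351, and was 3013 in the fit of all arrays, which pools the wider IP spread. Lists called in IP versus Rh1 heads (12) ran from 11 to 15 with 1 array left out, were 9 with the filter at the 50th percentile, 10 against CS heads and 13 with rtp, and were 0 with an estimated correlation in camera (7 at an unadjusted p under 0.05) and 15 with fry. Those in Rh1 heads versus CS heads (3) ran from 3 to 4 with 1 array left out, were 2 without a filter, where the pan-neuronal list had adjusted p = 0.105 (range over all alternatives 0.000509 to 0.434), 1 with an estimated correlation and 10 with fry, which asks another question. With a replicate block over numbers 1 to 4 of the head groups 4699 probe sets and 5 lists passed. Same-numbered arrays did not deviate together (correlations -0.083, -0.03, -0.081 and 0.056, none the best match), so they share only a number.

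With CS heads as reference the IP folds turned for trpl (-0.51), trp (-0.11), Arr1 (-0.94), Arr2 (-0.36), inaD (-0.19) and the phototransduction median (-0.51), since these are higher in CS heads. The other changes of direction were of results not past the threshold on either side, and their cause was not tested. For lists it is camera's direction that changed, or fry's, and the values are medians. In IP versus Rh1 heads, the clock median (-0.09) was -0.06 with the filter at the 50th percentile, -0.05 with median scaling, 0.14 against CS heads, -0.18 without IP replicates 2 and 4 and -0.09 with fry, and -0.08 each without Rh1 head replicate 1, Rh1 head replicate 4 or IP replicate 2, within -0.16 to -0.05 with 1 array left out. The fold of repo was -0.09 without the arrays whose titles end in R, and ran from -0.14 (without Rh1 head replicate 1) to 0.16 with 1 array left out. In Rh1 heads versus CS heads, hemocytes had -0.01 with pseudocount 1, 0.03 with array weights, 0.01 with the replicate block and 0.10 with the mean of all probe sets, and -0.01, 0.02 and 0.00 without CS head replicate 2, CS head replicate 5 or Rh1 head replicate 3. Without a filter, brain transmitter systems had 0.09 and antenna 0.02, ribosomal proteins had 0.00 with cyclic loess, and muscle -0.03 without CS head replicate 4. Signal over background limits the low genes, whose folds shrink toward 0.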

Other observations

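Chosen after their values were seen, 2 further eye genes were, like trp and trpl, lower in Rh1 heads than in CS heads and higher in IP than in Rh1 heads. The first, rtp, was planned for the phototransduction list but left out of it by its spelling, and the other, Cpn, was in no list. The retinophilin gene rtp had a signal of 6654 ± 481 (SD, n = 6) in CS heads, 1584 ± 106 (SD, n = 4) in Rh1 heads and 8924 ± 680 (SD, n = 4) in IP. Cpn, which encodes the photoreceptor calcium-binding protein calphotin, had 2698 ± 537 (SD, n = 6), 751.1 ± 87.9 (SD, n = 4) and 3808 ± 122 (SD, n = 4). The log2 folds of Rh1 heads minus CS heads were -2.05 (SE 0.07) for rtp and -1.79 (SE 0.12) for Cpn.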
